A study of Mus musculus with 4 samples.

How the data were processed

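RNA was sequenced from aorta of 3-week-old C57BL/6 mice, 2 libraries from wild-type mice and 2 from mice with a knockout of the gene for geranylgeranyl diphosphate synthase (GGPPS, gene symbol Ggps1). Per the labels' protocols, polyadenylated RNA was selected with oligo-dT beads, fragmented, primed with random hexamers and made into Illumina libraries. The labels name both sexes for each library and do not say whether a library came from 1 animal or a pool. They do not give the cells in which the gene was deleted or the deleted exon. Libraries were grouped by the genotype label, and the numbers 1 and 2 within a genotype are names only and pair nothing.

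The deposited values are FPKM (fragment counts scaled for transcript length and for the mapped fragments of the library), 1 file per library, per the file headers, which carry a misspelt form of that unit. The submitters' processing notes name HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 1.16.1 and the genome build mm10, without saying which step used which tool. Which program turned fragments into FPKM, and whether counting used strand, is not given in the sources used here. Reads from a gene and an overlapping antisense gene may therefore not be told apart. Each file lists 24346 rows in one order, with 24344 distinct symbols. A pair of date-like symbols, as a spreadsheet makes from the names of MARCH genes, appear on more than 1 row each. Of all rows, 6804 were at 0 in the 4 libraries. Eln, the elastin gene, which aortic cells use heavily, was among them, so a 0 in these files is reported only as a listed value. Mitochondrially encoded genes were not analysed here.

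Low values were searched for a common step that would show whole fragments. Among genes under 0.3 FPKM in both libraries of a pair, the most frequent ratio of the pair's values, taken to 3 decimals, covered between 0.302% and 0.464% of 1648 to 2188 genes. No step was found, so fragment counts were not recovered and the depth of each library is unknown. No interval or detection limit that needs depth is given. The test chosen before the data were examined assumed counts. As the unit is FPKM, the test named beforehand for that case was used, which is limma 3.58.1 (R 4.3.3) with an intensity trend, on log2(FPKM + 1). A count model was not used here. Fold changes are on the log2(FPKM + 1) scale, knockout minus wild type, which understates the change of genes with low values. Where a named gene is given as a fold higher or lower, the fold is the ratio of the mean FPKM of the genotypes without the pseudocount, which is larger for genes with low values. Genes with at least 1 FPKM in at least 2 libraries were tested, 12314 in all, with Benjamini-Hochberg adjustment over them and a threshold of 0.05. A gene under 1 FPKM in both wild-type libraries was tested only if both knockout libraries reached it. Such a gene could not count as a fall. The reverse holds for genes under 1 FPKM in both knockout libraries. The limma p-values measure the spread between these libraries, with each gene's variance drawn toward the trend over all genes. Xist and Y-linked genes were present in each library, so each held RNA of both sexes and of more than 1 animal. The spread is thus one between pools. It may still be partly technical, since nothing says that the pools shared no animals. An exact permutation test of 2 libraries against 2 cannot give a two-sided p under 0.333, so none was used.

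Before the data were examined, 52 gene lists were fixed: pathways, markers of cell types that an aorta dissection could hold, and controls. The 42 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 between genes, adjusted over those lists. At that setting camera treats genes as nearly independent. Its p-values then rest on the spread across genes and are not evidence from replicate libraries. Members called by the gene test were counted over all genes tested and adjusted over the list alone. The alternatives were camera with a correlation estimated per list and fry. Genes named were Ggps1, the 10 largest rises and 10 largest falls, the 5 most abundant genes called in each direction, and up to 4 called members of each list by smallest p. The largest changes were taken among called genes with a mean of at least 5 FPKM, with both libraries of one genotype above both of the other, and without predicted-gene symbols or sex-linked genes. Lists with no called member could give up to 2 genes, and the sex-linked and immediate early lists served as checks. The mean in this rule was first set for CPM, a scaled count, and is read here as FPKM, and it does not apply to genes named from lists. Where 5 or fewer members of a called list went against it, they were named after their values were seen, as were the genes Csf1r, Cd163 and Mrc1. Some genes that this rule names are not reported here. Lists of NRF2 targets, of ATF4 targets and of general leukocyte genes were added after the main results were seen, without genes whose values were known.

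Gene coordinates, transcript length and GC content came from the GENCODE M21 annotation of the mouse mm10 assembly, matched by symbol for 23284 symbols and by RefSeq synonym for 665. Transcript length and GC were known for 99.3% of tested genes. The alternatives tried were median-of-ratios, upper-quartile and column-total scaling, no filter, robust estimation, removal of the sex-linked and erythroid lists, each library left out, a threshold of 0.01 and a minimum fold of 1.5. Added after the data were seen were pseudocounts of 0.1 and 5, a filter of 5 FPKM, and removal of a loess trend on length and GC from each library. A comparison of 2 libraries against 2 was simulated 20 times over 12314 genes, with 200 changed and gene variances drawn from the fitted prior. There limma called 46.6% of genes changed 1.5-fold, 88.1% of those changed 2-fold and 99.3% of those changed 4-fold. Of the genes called there, 5.89% were unchanged. In the data 65.8% of tested genes were called, which makes the adjusted threshold less strict than with 200 changed genes. These percentages therefore do not describe recovery or false calls in the data. Recovery depends on the variances assumed: 20 simulations with wider gene variances, the version run first, called 16.3%, 66.6% and 95.0% of genes changed 1.5-fold, 2-fold and 4-fold. Plots were drawn with matplotlib 3.10.9.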

Results

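Transcript levels were measured in 4 aorta libraries of 3-week-old mice, 2 wild type and 2 GGPPS knockout. GGPPS makes geranylgeranyl diphosphate, the lipid that is attached to many small GTPases. The FPKM values summed to 515927 and 520478 in the wild-type libraries and to 611767 and 632918 in the knockout libraries. The 2 wild-type libraries had a Pearson correlation of 0.996 across tested genes and the knockout libraries 0.994, against 0.884 to 0.897 between genotypes. Genes are not independent replicates in these values. Between 0.114% and 0.171% of genes differed more than 2-fold on the log2(FPKM + 1) scale within a genotype, and 18.5% to 20.1% did so between genotypes. Rn45s, a ribosomal RNA precursor, stood at 3353 and 1942 FPKM in wild type and 2979 and 1317 FPKM in knockout.

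The comparison asked how the aortic transcriptome differed between GGPPS knockout and wild type. Ggps1 (mm10 chromosome 13, 14050659 to 14063488, minus strand, 4 exons in its longest transcript) was at 8.96 and 10.6 FPKM in the wild-type libraries and 1.18 and 1.07 FPKM in the knockout libraries, in the direction of the labels. Its level fell by 2.34 on the log2 scale (SE 0.13, limma adjusted p = 3.5e-09). Genes of contractile smooth muscle fell in 27 of 27 cases (camera adjusted p = 9.11e-15, and adjusted p = 0.526 with an estimated correlation), among them Acta2, smooth muscle actin, from 6857 ± 819.9 to 1420.0 ± 524 FPKM (mean ± SD, n = 2 per genotype). Spp1, the matrix protein osteopontin, rose from 0.110 ± 0.069 to 929.6 ± 108 FPKM. Mgp, a matrix protein that inhibits calcification, rose from 4625 ± 259 to 21043 ± 179 FPKM and took 3.46% and 3.30% of all FPKM in the knockout libraries. Interferon-response genes rose in 29 of 29 cases and ribosomal protein genes in 36 of 36. G2/M cell cycle genes rose in 27 of 28 and macrophage genes in 19 of 21. Each list was past the threshold by camera at the preset correlation and not with an estimated one. The interferon, G2/M and macrophage counts include genes that passed the filter wholly or partly through the knockout libraries.

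Of 12314 genes tested, 4332 were higher and 3764 lower in knockout at a limma adjusted p under 0.05, 65.8% of the total. On the log2(FPKM + 1) scale, at least 2-fold changes were found for 1341 of the higher and 938 of the lower genes, and at least 8-fold changes for 96 and 4. By the ratio of mean FPKM, the scale of the folds given for named genes, these counts were 1676 and 1394, and 383 and 48. With column totals made equal the split was 3116 higher and 5580 lower, and the median log2 fold change of all tested genes moved from 0.03 to -0.20. Because depth is unknown, precision rests on the spread between 2 libraries per genotype, with each gene's variance drawn by limma toward the trend over all genes. The total degrees of freedom were 13.4, of which 2 came from a gene's own libraries and the rest from other genes.

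**Figure D1:**
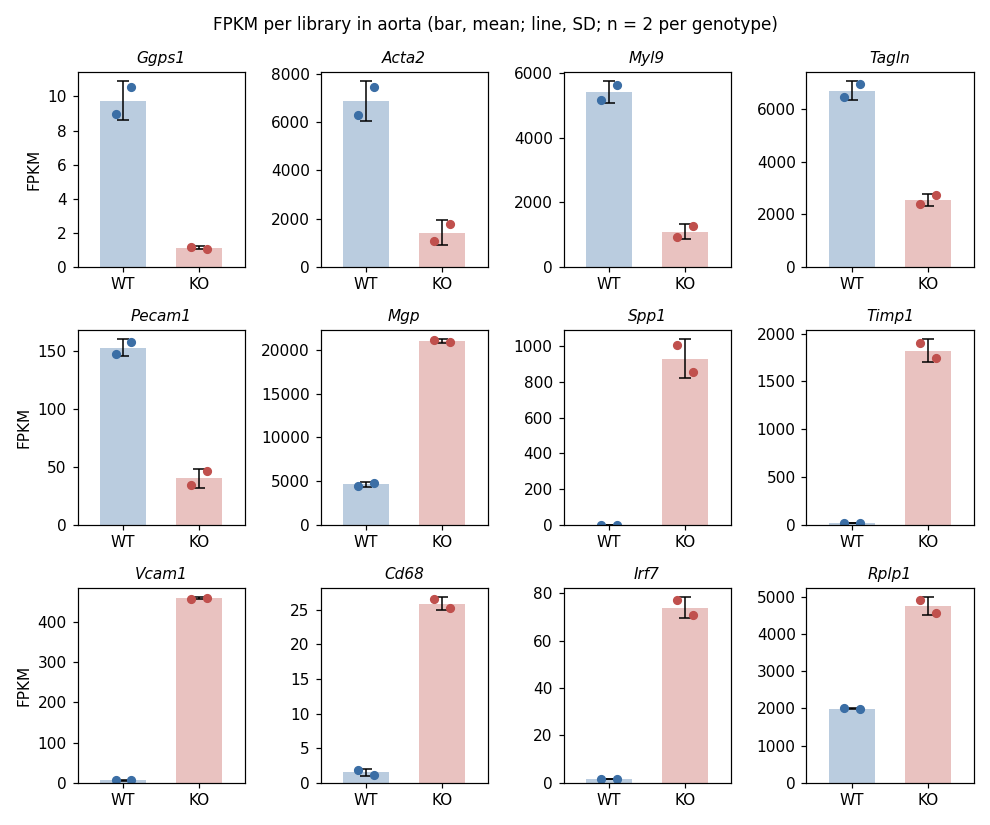
FPKM of 12 genes in wild-type (WT) and knockout (KO) aorta, each panel with its own linear axis from 0; bars are means, lines are 1 SD and points are the 2 libraries of each genotype. Ggps1 stands near 9.75 FPKM in wild type and 1.12 in knockout, and Mgp near 4625 and 21043.

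Gdf15, a stress-induced cytokine, was among the largest rises, from 1.91 ± 0.14 to 273 ± 25.3 FPKM. Timp1, an inhibitor of matrix metalloproteases (chromosome X, 20870166 to 20874735), rose 85.8-fold from 21.3 ± 1.25 to 1823 ± 117 FPKM (log2 fold change 6.36, SE 0.10, limma adjusted p = 2.52e-14). Vcam1, an adhesion molecule for leukocytes, rose 68.5-fold and Hmox1, heme oxygenase, 58.7-fold. Lgals3, galectin-3, rose 47.8-fold and reached 399 ± 38.6 FPKM. Gsta1, a glutathione transferase, was listed at 0 in both wild-type libraries and at 69.2 and 74.1 FPKM in knockout, and it has near-identical copies, so its level is uncertain. Its relative Gsta4 rose by 6.13 on the log2 scale and Anxa8, an annexin, by 5.38.

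Among the largest falls was Tcap, a sarcomere protein, from 171 ± 52.6 to 14.2 ± 7.91 FPKM. Sost, the secreted Wnt inhibitor sclerostin, fell from 667.7 ± 21.5 to 67.5 ± 26.3 FPKM (log2 fold change -3.34, SE 0.18, limma adjusted p = 2.91e-09). Adra1d, an alpha-1 adrenergic receptor, fell 9.71-fold and Scube3, a secreted glycoprotein, 7.80-fold. Pcp4l1 fell by 2.98, Angptl7 by 2.95 and Adam11 by 2.87 on the log2 scale. Sparcl1, Ppp1r1b and Rhobtb1 each fell by 2.80. These rises and falls were chosen among genes with both libraries of one genotype above both of the other.

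All 27 tested genes of the contractile smooth muscle list were lower in knockout, with a median log2 fold change of -2.05 (camera adjusted p = 9.11e-15, and adjusted p = 0.526 with an estimated correlation). The list took 7.01% and 7.54% of all FPKM in wild type and 1.65% and 2.02% in knockout. Tagln, an actin-binding protein, fell from 6706 ± 353 to 2554 ± 231 FPKM and the myosin light chain Myl9 from 5408 ± 329 to 1089.8 ± 237. Lmod1 fell by 2.11, Synpo2 by 2.77 and Csrp1 by 1.87 on the log2 scale. Myl6 fell from 7437 ± 152 to 3510.0 ± 258 FPKM. Markers of neighbouring cells were lower as well. Endothelial genes fell in 15 of 19 cases (median -1.20, camera adjusted p = 6.74e-06, and adjusted p = 0.421 with an estimated correlation), among them Pecam1 from 152.6 ± 7.29 to 40.1 ± 8.43 FPKM and Vwf from 28.3 ± 1.86 to 9.70 ± 0.67 (log2 fold change -1.45, and -0.83 with length and GC trends removed). Plvap rose from 16.8 ± 0.22 to 42.1 ± 0.11. Fibroblast genes fell in 12 of 17 cases (median -1.08, camera adjusted p = 0.00115, and adjusted p = 0.487 with an estimated correlation), with Clec3b 3.32-fold lower and Lum among the risers. Lox was counted as a riser at a log2 fold change of 0.29, and its call ended in 7 of 14 alternatives of the gene test. Its values were 0.22 without wild-type library 2 (limma adjusted p = 0.211), 0.096 without knockout library 2 (0.399) and 0.027 with equal column totals (0.848), over a range of 0.027 to 0.48. Pericyte genes fell in 6 of 7 (median -0.90, camera adjusted p = 0.00693, and adjusted p = 0.388 with an estimated correlation), with Anpep higher, a call that ended without wild-type library 1 and with equal column totals (limma adjusted p = 0.0976 and 0.0781). Skeletal muscle genes fell in 4 of 5 (median -1.27, camera adjusted p = 0.0265, and adjusted p = 0.421 with an estimated correlation), each with low FPKM, such as Ckm at 3.13 ± 0.85 and 0.141 ± 0.163.

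Genes of modulated smooth muscle, a list of genes known to rise when these cells leave the contractile state, rose in 14 of 18 cases and fell in 3 (median 2.18, camera adjusted p = 3.02e-06, and adjusted p = 0.387 with an estimated correlation). Besides Spp1, Timp1 and Vcam1, Thbs1, thrombospondin 1, rose from 14.0 ± 0.64 to 369 ± 26.7 FPKM. The 3 that fell were Myh10, Vim and Vcan. The fall of Vim, -0.35 on the log2 scale, was -0.18 without wild-type library 2 (limma adjusted p = 0.25) and -0.16 without knockout library 1 (0.427), and its call also ended with no filter (0.182) and robust estimation (0.121). Macrophage markers rose in the same libraries in 19 of 21 cases (median 2.36) and general leukocyte genes, a list added after the main results were seen, in 17 of 17 (median 1.45). Spp1 and Lgals3 are known to be made by macrophages too.

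Isoprenoid and sterol synthesis genes rose in 18 of 25 cases (median 0.56, camera adjusted p = 0.00321, and adjusted p = 0.387 with an estimated correlation), with a median of 0.35 at equal column totals and 0.29 with a pseudocount of 5. Fdps, which makes the substrate of GGPPS, rose from 27.0 ± 2.83 to 91.6 ± 1.01 FPKM. Msmo1 rose by 1.63 and Insig1, a regulator of sterol synthesis, by 1.29 on the log2 scale. The 2 that fell were Ggps1 itself and Tm7sf2. Prenyl transfer genes rose in 7 of 18 cases and small GTPase genes rose in 16 and fell in 6 of 26, and neither list passed (camera adjusted p = 0.352 and 0.153). The prenyl median was 0.14, and -0.10 with equal column totals. It was 0.078 without wild-type library 1, 0.25 without knockout library 1 and 0.058 without knockout library 2. By fry, which tests whether a list's genes move one way on balance and not against other genes, the small GTPase list passed as higher (adjusted p = 0.0429). Of its genes, Rhoc rose from 385 ± 18.7 to 705 ± 32.8 FPKM and Rac2, the leukocyte Rac, from 0.238 ± 0.008 to 3.49 ± 0.76. Beside these lists, macrophage and general leukocyte genes rose (medians 2.36 and 1.45) and contractile smooth muscle genes fell (median -2.05).

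All 29 tested interferon-response genes were higher in knockout (median 2.68, camera adjusted p = 9.11e-15, and adjusted p = 0.358 with an estimated correlation). Irf7, the interferon regulatory factor, rose from 1.73 ± 0.001 to 73.8 ± 4.39 FPKM and Ifit3 from 4.82 ± 0.026 to 108.7 ± 6.98. Antigen presentation genes rose in 14 of 15 cases (median 1.85, camera adjusted p = 4.42e-07, and adjusted p = 0.358 with an estimated correlation), including Cd74 from 7.62 ± 0.77 to 61.9 ± 6.92 FPKM. Chemokines and cytokines rose in 17 of 23 (median 1.31, camera adjusted p = 5.14e-06, and adjusted p = 0.421 with an estimated correlation), with a median of 2.09 under a filter of 5 FPKM and of 0.60 and 2.67 with pseudocounts of 5 and 0.1. Ccl2 reached 32.6 ± 2.47 FPKM from 0.470 ± 0.039, and the 2 that fell were Ccl11 and Icam1. The Icam1 call ended in 4 of 14 alternatives, among them without wild-type library 1 or 2 or knockout library 2 (limma adjusted p = 0.154, 0.28 and 0.0687). Macrophage markers rose in 19 of 21 (median 2.36, camera adjusted p = 6.42e-09, and adjusted p = 0.358 with an estimated correlation). Lyz2, lysozyme, rose from 21.1 ± 1.67 to 152 ± 19.2 FPKM and Cd68 from 1.52 ± 0.50 to 25.9 ± 0.91. Mertk was lower, and Cd163 was at 1.58 ± 0.32 and 1.24 ± 0.35. With a pseudocount of 5, which shrinks the change of low genes, the interferon-response median was 1.35 and the macrophage median 1.24. A wild-type mean of at least 1 FPKM was reached by 18 interferon-response and 14 macrophage genes. It was reached by 13 of the 38 chemokine and cytokine genes in the files, 23 of which were tested. Tested genes below it passed the filter wholly or partly through the knockout libraries, so these counts of rises lean on the filter. No tested gene remained in the T and NK cell or B cell lists, whose 14 and 8 members in the files stayed under 1 FPKM.

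**Figure D2:**
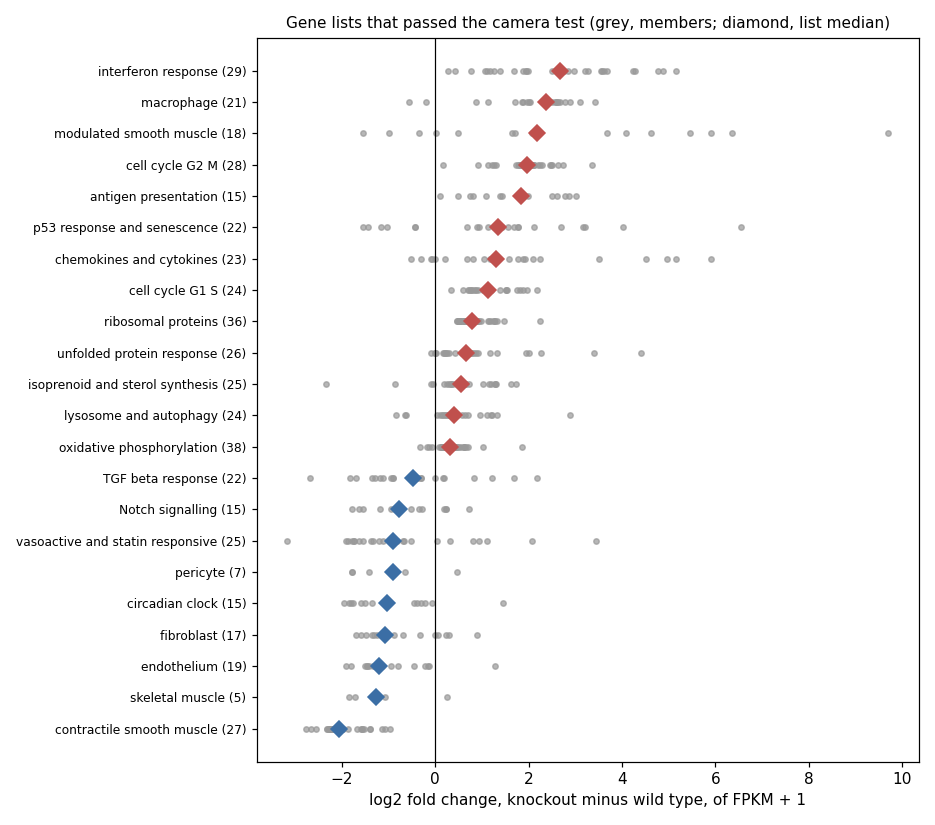
Log2 fold change of FPKM + 1, knockout minus wild type, for the 22 lists that passed camera, with the number of tested members in brackets; grey points are genes and diamonds are list medians. The interferon-response median is at 2.68 and the contractile smooth muscle median at -2.05, and the oxidative phosphorylation median of 0.31 drops to -0.00037 once length and GC trends are removed.

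All 24 tested genes of the G1/S list (median 1.14, camera adjusted p = 4.83e-08, and adjusted p = 0.358 with an estimated correlation) and 27 of 28 of the G2/M list (median 1.97, camera adjusted p = 3.23e-12, and adjusted p = 0.421 with an estimated correlation) were higher. Ube2c rose from 2.77 ± 0.59 to 37.6 ± 3.52 FPKM and Mcm5, part of the replicative helicase, from 2.31 ± 0.09 to 11.1 ± 0.09. With a pseudocount of 5 the G1/S and G2/M medians were 0.67 and 0.95. A wild-type mean of at least 1 FPKM was reached by 19 of the 24 G1/S genes and 14 of the 28 G2/M genes. The others passed the filter wholly or partly through the knockout libraries, so these counts lean on the filter. Macrophage markers (median 2.36, 19 of 21 higher) and general leukocyte genes (median 1.45, 17 of 17 higher) rose in the same libraries. The p53 and senescence list rose in 16 and fell in 6 of 22 cases (median 1.35, camera adjusted p = 0.00115, and adjusted p = 0.358 with an estimated correlation), with Gadd45a, a DNA damage response gene, 19.5-fold higher and Cdkn2b, an inhibitor of the cell cycle, from 0.889 ± 0.203 to 15.8 ± 0.77. Unfolded protein response genes rose in 17 of 26 (median 0.65, camera adjusted p = 5.89e-05, and adjusted p = 0.573 with an estimated correlation), with a median of 0.40 at equal column totals. The leading genes, Trib3 and Chac1, rose by 4.41 and 3.39 on the log2 scale.

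All 36 ribosomal protein genes of the list were higher (median 0.78, camera adjusted p = 4.41e-10, and adjusted p = 0.358 with an estimated correlation), and the list held 5.93% and 5.98% of FPKM in wild type and 9.02% and 8.60% in knockout. Rplp1 rose from 1989 ± 11.1 to 4739 ± 239.6 FPKM and Rpl41 2.29-fold. With length and GC trends removed the list median was 0.43, and with equal column totals it was 0.52. These genes have many near-identical pseudogenes, so single values are uncertain. Rps27rt, a copy of Rps27, was 0.48 higher on the log2 scale and at -0.21 with length and GC trends removed (limma adjusted p = 0.162), and its call also ended with equal column totals (0.0806). Lysosome and autophagy genes rose in 15 of 24 cases (median 0.41, and 0.15 with equal column totals, camera adjusted p = 0.013, and adjusted p = 0.573 with an estimated correlation), led by Sqstm1, an autophagy receptor, from 123.9 ± 3.95 to 922 ± 10.3 FPKM. The 3 that fell were Tfeb, Map1lc3a and Ulk1. The macrophage and general leukocyte lists, medians 2.36 and 1.45, rose beside these genes. Oxidative phosphorylation genes rose in 23 of 38 cases, with Ndufb10 lower (median 0.31, camera adjusted p = 0.00298, and adjusted p = 0.546 with an estimated correlation). This call ended with equal column totals (median 0.05, adjusted p = 0.0704), without wild-type library 1 or 2 (adjusted p = 0.0761 and 0.0932) and with length and GC trends removed (adjusted p = 0.704), over a range of 0.000596 to 0.704 by camera or fry. The Ndufb10 call ended without wild-type library 2 or knockout library 1 and with no filter (limma adjusted p = 0.391, 0.367 and 0.148).

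Vasoactive genes fell in 18 and rose in 6 of 25 cases (median -0.90, camera adjusted p = 0.00228, and adjusted p = 0.573 with an estimated correlation), with Edn1, endothelin 1, from 15.5 ± 1.73 to 3.40 ± 0.21 FPKM and Ptgs2 from 1.71 ± 0.26 up to 28.3 ± 3.41. Notch genes fell in 10 of 15 (median -0.77, camera adjusted p = 0.00733, and adjusted p = 0.573 with an estimated correlation), including Notch3 by 1.78 on the log2 scale and by 1.13 with length and GC trends removed, with Notch4 higher. TGF-beta response genes fell in 14 and rose in 4 of 22 (median -0.48, camera adjusted p = 0.0265, and adjusted p = 0.669 with an estimated correlation), with Id2 6.30-fold lower and Bhlhe40, Tgfb1 and Ltbp2 among those higher. Circadian clock genes fell in 11 of 15 (median -1.04, camera adjusted p = 0.000182, and adjusted p = 0.358 with an estimated correlation). Nr1d1 fell from 109 ± 10.5 to 29.6 ± 0.72 FPKM and Per2 by 1.76 on the log2 scale, while Arntl rose from 1.41 ± 0.008 to 5.62 ± 0.28. With a pseudocount of 5 the vasoactive median was -0.54 and the Notch median -0.34. Cell type lists that fell in the same libraries were contractile smooth muscle (median -2.05), endothelium (-1.20), fibroblast (-1.08) and pericyte (-0.90). The hour of collection is not given in the sources used here.

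Matrix lists were mixed and did not pass by camera. Collagen genes rose in 11 and fell in 14 of 29 cases (camera adjusted p = 0.282), with Col8a1 22.0-fold higher and Col18a1 2.79-fold lower. Elastic fibre genes rose in 7 and fell in 8 of 19 (camera adjusted p = 0.27), with Fbln2 6.68-fold higher and Mfap4 2.93-fold lower, and Eln was listed at 0 in the 4 libraries. Matrix proteases and inhibitors rose in 16 and fell in 12 of 30 (camera adjusted p = 0.278). By fry the protease list passed as higher (adjusted p = 0.00876). The protease median was 0.25, and -0.013 with equal column totals. With length and GC trends removed, the collagen median moved from -0.26 to 0.13 and the elastic fibre median from -0.15 to 0.057. The collagen median was -0.14 without knockout library 1, and the elastic fibre median -0.10 without wild-type library 1 and -0.25 without wild-type library 2. With equal column totals they were -0.52 and -0.41. The bone and cartilage list rose in 3 and fell in 7 of 13 (camera adjusted p = 0.0789), where Sox9 rose from 0.572 ± 0.092 to 10.5 ± 0.23 FPKM and Alpl, alkaline phosphatase, fell from 6.74 ± 1.86 to 0.868 ± 0.156. Calcification inhibitors rose in 7 and fell in 4 of 11 (camera adjusted p = 0.32), with Tnfrsf11b, osteoprotegerin, 25.4-fold higher, and passed as higher by fry (adjusted p = 0.00609). Without wild-type library 1 or 2, the calcification inhibitor median was 0.37 and 0.32, against 0.33 with all libraries. That of the proteases was then 0.27 and 0.21. The bone and cartilage median was -0.59 and -0.41, against -0.37 with all libraries.

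The counts adjusted over the list alone were equal to those over all genes in 18 of the 22 lists that passed. They gave 15 falls for TGF-beta response, 11 for Notch and 12 for the clock list, and 3 rises for fibroblast. Of lists that did not pass, they gave 15 falls for collagens, 6 for glycolysis and 7 for hypoxia, and 5 rises for prenyl transfer. The skeletal muscle call ended under 3 scalings (camera adjusted p = 0.0553, 0.0587 and 0.0971) and without knockout library 1 or 2 (0.0502 and 0.0708), over a range of 0.00216 to 0.0971, and its median was -0.60 with a pseudocount of 5. The isoprenoid call ended without wild-type library 1 (adjusted p = 0.0583, range 0.00179 to 0.0583 by camera or fry). The vasoactive call ended with fry (adjusted p = 0.0598, camera and fry range 0.000507 to 0.0598). The Notch call ended by camera with length and GC trends removed (median -0.23, adjusted p = 0.0843, range 0.0043 to 0.0843). The TGF-beta response call ended with those trends removed (median -0.40, camera adjusted p = 0.108), with equal column totals (median -0.73, 0.0816) and with fry (0.176), over a range of 0.0157 to 0.176. These ranges leave out the estimated correlation.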

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

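Pseudocounts, the 5 FPKM filter, the length and GC correction, and upper-quartile and column-total scaling of lists were chosen after seeing the data. DESeq2, limma-voom and thinning of libraries need counts and were not run, and the filter of 1 in 2 libraries is the one already in use. Ggps1 fell under all 14 other settings of the gene test with a log2 fold change between -3.01 and -1.27, and from -2.44 to -2.23 with each library left out. With a library left out, 3584 to 4427 genes were higher and 3045 to 3996 lower, and 13 to 15 lists were higher and 8 to 11 lower. A lone library is then assumed to vary like the other genotype, so calls and p-values of these fits are not comparable with the main ones. Against a minimum fold of 1.5, 1632 genes were higher and 1146 lower, since smaller changes are no longer called. With a correlation estimated per list, 0 lists were higher and 0 lower by camera (5 had an unadjusted p under 0.05, and fry called 28), with adjusted p from 0.358 to 0.669 for the 22 lists; 2 residual degrees of freedom carry that estimate. The estimated correlation was 0.88 for the contractile list, 0.34 for G2/M, 0.064 for interferon response and -0.0135 for ribosomal proteins. By fry, which does not compare a list with other genes, 21 lists were higher. Its 8 added calls were small GTPases (adjusted p = 0.0429), calcification inhibitors (0.00609), matrix proteases (0.00876), complement (0.00912), apoptosis (0.0117), glycolysis (0.0295), hypoxia (0.0219) and immediate early (0.0429), all as higher, although the hypoxia and immediate early medians were near 0 (-0.0084 and -0.0079, and 0.11 and 0.0945 without knockout library 1). Over the other 12 alternatives, 16 of the 22 lists stayed past the threshold each time (camera or fry adjusted p up to 0.0395), and skeletal muscle, isoprenoid, TGF-beta response, Notch, vasoactive and oxidative phosphorylation lost a call. Without wild-type library 1 or 2, further lists gained a call although medians such as that of complement stayed at 0.47. Such calls lean on the spread of the knockout pair and are not read as results. Calls that ended with a library left out carry the same limit, also where their adjusted p enters a range given above. Skeletal muscle had too few tested genes under the 5 FPKM filter. With length and GC trends removed, the oxidative phosphorylation median changed sign to -0.00037 (camera adjusted p = 0.704), and Rps27rt to -0.21 and Col11a2 to 0.24 (limma adjusted p = 0.162 and 0.0664), none of them past the threshold any longer. Fosl2 moved from -0.0079 (limma adjusted p = 0.958) to 0.37 (0.00958). Of all called genes, 10 were then called in the opposite direction. The cause was not tested. For the 242 named genes, 3278 of 3351 values kept direction and side of the threshold.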

Other observations

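The tests of smooth muscle cell loss, of scaling for the contractile and macrophage lists, and of macrophage type were chosen only after the results were seen, and so were the lists of NRF2 targets, ATF4 targets and general leukocyte genes. Lists that the text has not described gave mixed results by camera. Glycolysis genes rose in 11 and fell in 5 of 19 cases (camera adjusted p = 0.27), with Pgk1 3.73-fold and Gapdh 2.43-fold higher. Fatty acid oxidation genes rose in 2 and fell in 7 of 20 (camera adjusted p = 0.299), with Pdk4 2.86-fold lower. Hypoxia genes rose in 7 and fell in 6 of 18 (camera adjusted p = 0.847), angiogenesis genes rose in 8 and fell in 13 of 27 (adjusted p = 0.195), and YAP/TAZ targets rose in 5 and fell in 8 of 21 (adjusted p = 0.309). Median and mean differ in sign for the hypoxia (-0.0084 and 0.27), adipocyte (0.0076 and -0.15), immediate early (-0.0079 and 0.43) and Schwann lists. The first 3 medians lie near 0 and 1 library turns their sign: hypoxia was at 0.066 without wild-type library 1 and 0.11 without knockout library 1, adipocyte at -0.15 without wild-type library 2, and immediate early at 0.0945 without knockout library 1. Complement genes rose in 9 and fell in 6 of 17 (camera adjusted p = 0.268), with C1qa, also in the macrophage list, 5.92-fold higher, and apoptosis genes rose in 11 and fell in 6 of 21 (adjusted p = 0.34). Fry, which does not compare a list with other genes, called the glycolysis, hypoxia, complement and apoptosis lists higher (fry adjusted p = 0.0295, 0.0219, 0.00912 and 0.0117). Without wild-type library 1 or 2, the complement median was 0.47 each time, as with all libraries.

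Other cell types gave few genes. Adipocyte genes rose in 3 and fell in 3 of 10 (camera adjusted p = 0.658), and brown fat genes rose in 1 and fell in 4 of 5 (adjusted p = 0.137). The brown fat median was -0.67, and from -1.19 to -0.35 with each library left out. Cardiac muscle genes rose in 2 and fell in 3 of 5 (camera adjusted p = 0.455), with Tnnt2 7.03-fold higher. Schwann and neuron genes rose in 3 and fell in 4 of 7 (camera adjusted p = 0.652, median -0.54, or -0.28 with a pseudocount of 5, and mean 0.32), with Tubb3 from 0.292 ± 0.172 to 19.9 ± 3.28 FPKM. Immediate early genes rose in 10 and fell in 10 of 21 (camera adjusted p = 0.538, fry adjusted p = 0.0429 as higher). Fosl1 rose to 12.3 ± 1.45 FPKM from 0.060 ± 0.057, and Fos fell from 12.1 ± 0.91 to 6.30 ± 2.47, by 0.88 on the log2 scale and by 0.53 without knockout library 1. Fewer than 5 members were tested for the lymphatic, neutrophil, mast cell, erythroid, mesothelium, lymphoid organ and cartilage lists. Of these, Pdpn rose from 3.46 ± 0.20 to 13.8 ± 0.63 FPKM and Cd1d1 from 0.462 ± 0.235 to 2.45 ± 0.13, by 1.73 and 1.25 on the log2 scale. Kit fell from 2.32 ± 0.68 to 0.515 ± 0.158 FPKM, by 1.12 on the log2 scale, and Krt18 was 1.42-fold lower, the last with a limma adjusted p of 0.0579 without wild-type library 1. Hba-a2 was at 80.3 and 74.3 FPKM in wild type and 44.1 and 71.2 in knockout, and S100a8, a neutrophil gene, was at most 1.65 FPKM in a library. Among cartilage genes Hapln1 fell from 2.17 ± 0.15 to 0.660 ± 0.151 FPKM, by 0.94 on the log2 scale. Xist stood at 8.45 and 30.0 FPKM in wild type and 21.9 and 35.2 in knockout, and Ddx3y at 19.3, 9.49, 11.4 and 9.89, so both were present in each library, and neither passed (limma adjusted p = 0.0902 and 0.196). Without wild-type library 2, Xist was at 1.61 and Ddx3y at -0.81 on the log2 scale, and without library 1 they stood at -0.11 and 0.14. Ddx3y passed at -0.58 with equal column totals, and Xist at 1.29 with length and GC trends removed (limma adjusted p = 0.0415 and 0.0221). The other tested sex-linked genes, all Y-linked, were lower: Kdm5d at 3.34, 2.03, 1.27 and 1.01 FPKM, Eif2s3y at 38.2, 21.3, 16.6 and 15.1, and Uty at 2.97, 1.30, 1.01 and 1.10 (limma adjusted p = 0.000855, 0.0021 and 0.0214). Their calls ended in 1 of 12, 5 of 13 and 6 of 12 alternatives (limma adjusted p up to 0.0557, 0.104 and 0.421). Without wild-type library 1 the log2 fold changes were -0.50, -0.40 and -0.17, against -0.76, -0.81 and -0.56 with it. Wild-type library 1 held less Xist and more of each tested Y-linked gene than library 2, so the mix of the sexes differed between them. The lower Y-linked values in knockout were not told apart from such a difference in mix. The sex-linked list did not pass (camera adjusted p = 0.278).

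The fall of contractile genes was weighed against 3 explanations, of which scaling and the length and GC trend are technical. A loss of smooth muscle cells with the other cell types kept would raise markers of those types alike, but the endothelium median was -1.20 with 15 of 19 genes lower. Macrophage and general leukocyte medians did rise, at 2.36 and 1.45. Each scaling shifts all genes of a library alike. Under the 3 scalings the median of all tested genes lay between -0.20 and 0.0044, too little to undo a fall of this size. The contractile median closest to 0 over them was -2.08, and with length and GC trends removed it was -2.01 with 27 of 27 lower. Loss of smooth muscle cells together with a loss or dilution of endothelium stays open. Expression within the remaining cells was not tested and stays open too. Dilution by cells that increased, such as leukocytes, would lower the markers of every kept cell type by a like amount. Medians were -1.20 for endothelium, -1.08 for fibroblast and -0.90 for pericyte genes, against -2.05 for contractile genes. As medians, these values argue against dilution alone only if the other cell types kept their number and expression, which was not measured. The difference between the lists was not tested, and single genes overlap. Over the alternatives, the endothelial gene Pecam1 was at -2.18 to -1.71 and the contractile gene Tagln at -1.67 to -1.30. The medians therefore do not settle whether dilution alone was the source of the whole contractile fall. Dilution as a part of it stays open, as do the deleted cell type and the age at deletion.

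Ribosomal protein genes rose with a median of 0.78. Removing length and GC trends lowered it to 0.43 with 24 of 36 genes still higher, so this trend could account for part of the rise. A smooth trend fitted over all genes may under-correct short abundant ones, so the remainder does not show a rise beyond the trend. Lists of other genes near in length and level reached 0.78 in 32 of 10000 draws, with a median draw of 0.40, although these genes were less abundant (median log2 level 9.0 against 10.1). With equal column totals the median was 0.52. A rise beyond that of short abundant transcripts stays a hypothesis.

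Macrophage genes rose with a median of 2.36. Over 3 scalings, which shift all genes of a library alike and by too little to undo this rise, the median closest to 0 was 2.15. General leukocyte genes outside that list rose in 17 of 17 tested cases, of 20 listed, with a median of 1.45. The camera adjusted p was 2.96e-08, and 0.336 with an estimated correlation. Coro1a rose from 1.05 ± 0.31 to 25.0 ± 1.61 FPKM and Rgs10 from 9.13 ± 0.86 to 26.8 ± 3.91. Genes such as Ptprc, at 0.231 ± 0.016 and 2.39 ± 0.0015 FPKM, passed the filter through the knockout libraries alone. They could not count as falls, so the count of 17 is partly fixed by the filter. The rises go with more leukocytes in the knockout tissue. A larger share of macrophages like those of wild type stays open: the log2 fold changes of Csf1r and Cd163 differed by 2.18 (SE 0.19), but that pair was chosen after its values were seen, Cd163 stayed under 2 FPKM in each library, and Mrc1 rose from 1.56 ± 0.02 to 3.68 ± 0.32 FPKM. Other macrophage states and expression by other cells stay open as well, since 14 of the 21 macrophage genes reached a mean of 1 FPKM in wild-type aorta.

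Because Hmox1, Gsta4, Trib3 and Chac1 were among the strongest rises, joint rises of NRF2 and ATF4 targets were tested on genes whose values had not been seen. NRF2 targets rose in 20 of 22 cases with a median of 1.51 (camera adjusted p = 1.23e-07 over 45 lists, and 0.339 with an estimated correlation). Srxn1 rose from 10.2 ± 1.09 to 177 ± 7.60 FPKM and Gclm from 12.5 ± 1.13 to 86.5 ± 2.66, while Gstm1 fell. ATF4 targets of amino acid supply rose in 26 of 28 with a median of 1.17 (camera adjusted p = 8.72e-09, and 0.37 with an estimated correlation). Psph, an enzyme of serine synthesis, rose from 5.12 ± 0.48 to 25.4 ± 0.64 FPKM, while Slc1a5 and Vldlr fell. The Vldlr call ended without wild-type library 2 and with length and GC trends removed (limma adjusted p = 0.0521 and 0.128). With equal column totals the medians were 1.26 and 0.91. Both list results go with joint rises of these targets, and whether the factors themselves were active was not tested. In the same libraries the macrophage and general leukocyte medians were 2.36 and 1.45 and the contractile median -2.05. The rises were not told apart from a change in cell types.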
